A study of Mus musculus with 931 samples.

How the data were processed

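The study measured gene expression in mouse pancreatic islet cells at 7 stages, from E17.5 through P0, P3, P9, P15 and P18 to P60. Bulk RNA sequencing covered 14 libraries of sorted Ins1-RFP+ β cells, 2 per stage, made from poly(A) RNA with a strand-specific kit. Single cells were collected with the Smart-seq2 protocol, which reads whole transcripts and carries no molecular identifiers, from Ins1-RFP mice (β cells), Gcg-Cre; Rosa-RFP mice (α cells, not collected at P3) and Ngn3-GFP mice. Some cells were FACS-sorted and others were picked by hand, and the labels name the batch of each cell but no animal. Cells listed by the labels without a column in the count tables are not analysed here.

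The deposited values used here are raw read counts per gene, whole numbers with no normalization, in a table of bulk libraries and a table of 917 cells. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq 0.6.0 and DESeq 1.20.0 were used, with the genome builds GRCm38 and mm10. The notes state neither the role of each tool nor the strand setting of the counting, so counts of genes whose exons overlap those of another gene are uncertain. Each table held 40824 gene rows and 92 rows of ERCC spike-ins, synthetic RNAs added in known amounts. Spike-ins took a median of 2.72% of a cell's reads (range 0.676% to 12.3%) and were left out of every gene count and library size. The deposited TPM tables were not used: the single-cell one follows from the counts and gene lengths, and the bulk one is pooled over the libraries of a stage, which leaves no spread. No 2 columns were identical (0 pairs of bulk libraries, 0 pairs of cells).

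Cells were grouped by the labels. Unselected single-hormone cells numbered 866, in 45 batches: 538 β cells in 25 batches and 328 α cells in 20 batches, which made 13 groups of stage and cell type. A further 21 β cells in 2 batches were enriched for proliferating cells by single-cell RT-qPCR, 26 cells were labelled with more than 1 hormone, and 4 were Ngn3-GFP cells that the labels call negative for hormone. Reads were summed over the cells of a batch, and the batch, not the cell, was the replicate. The p-values therefore measure the spread between labelled batches, which may be technical. A batch held 5 to 39 cells and 5.96 M to 49.1 M reads. Bulk libraries held 10.3 M to 21.4 M reads, and single cells 0.521 M to 2.32 M (median 1.15 M) with 4715 to 11666 genes detected (median 7651). Reads are not independent molecules, so the intervals and the floors given for counts of 0 cover counting error only.

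Gene tests used edgeR 4.0.16 (quasi-likelihood, TMM normalization, low-count filter) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the call. All 14 bulk libraries stood in 1 fit with stage as the factor (16086 genes tested, common dispersion 0.0664). The 45 single-cell batches stood in 1 fit with stage and cell type as groups and the collection method as covariate (18537 genes, common dispersion 0.648). The enriched batches were added to that fit for their own comparison (20445 genes), each enriched batch being assumed to vary like the others. The Ins1+ Sst+ cells were compared with the single-hormone cells of the same 6 batches, with batch as the pair (14590 genes). Levels are CPM with TMM scaling, averaged over libraries or batches, and adjusted p-values are the edgeR ones unless another tool is named. A fold against a group with 0 reads was computed against a floor of 3 reads over the group, and no fold is given against a group of 1 to 3 reads. The exception is the fitted differences of log2 changes between α and β cells. These are printed as fitted, and those that hold groups near 0 reads are marked as no bounds.

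Before the data were examined, the comparisons, tests, gene lists, marker lists, alternatives and the rule for named genes were fixed. The rule took, per main comparison, the 5 largest rises and 5 largest falls among called genes with at least 20 CPM in the higher group and no overlap between groups. It added the 2 called members with the smallest p, at 5 CPM or more, of each of 14 gene lists, the member a list is named for, and Ins1, Ins2, Gcg, Sst, Ppy, Ghrl, Ucn3, Mafa and Mki67. Some genes that the rule names are not reported here. Predicted, ribosomal and mitochondrial genes were skipped among the largest changes. The lists were β function and maturity, immature endocrine, α identity, islet transcription factors, proliferation, β disallowed genes, oxidative phosphorylation, glycolysis, hormone secretion machinery, ER folding and stress, cholesterol synthesis, MHC class I and interferon, ribosomal proteins, and immediate early and heat shock genes. The lists share members, such as Rbp4 in the immature list and the δ cell markers. A further 10 marker lists covered δ, PP, ε, acinar, duct, endothelial, mesenchymal, immune, erythroid and Schwann cells. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, and with fry. Of 98 list tests over 7 comparisons, 52 passed with the preset correlation, 20 with the estimated correlation and 60 with fry, which asks only whether a list moves on balance 1 way.

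For the share of cells with proliferation genes, each cell was thinned to 500000 reads, and a cell counted when 5 or more of 43 list genes had a read. Batches at E17.5 to P9 were compared with batches at P15 to P60 by a two-sided permutation test of 100000 draws, or an exact test with fewer than 10 batches in a group. A cell was counted for Xist, or for the sum of 4 Y-linked genes, at 20 CPM or more. Gene positions are from GENCODE M21 on GRCm38. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

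The pipeline was tested on simulated data in which 200 genes had been changed by known folds. In the bulk design it called 86 genes, 4 of them unchanged (4.65%), and recovered 2% of 1.5-fold, 16% of 2-fold, 64% of 4-fold and 82% of 8-fold changes. In the single-cell β design it called 43, of which 2 were unchanged, and recovered 6%, 26% and 50% of the 2-fold, 4-fold and 8-fold changes. In the single-cell α design it called 49, of which 1 was unchanged, and recovered 16%, 38% and 40%. In the enriched design it called 24, of which 0 were unchanged, and recovered 2%, 16% and 30%. Genes that were not called may therefore have changed by several-fold.

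Replicate numbers were checked for shared days or litters. The residuals of bulk libraries with the same number had correlations of -0.139 to 0.427 across stage pairs (median 0.0486, over 0.1 in 7 of 21 pairs), and those of single-cell batches with the same number had a median of -0.000843. Numbers were therefore not used as pairs, and the blocked fits are among the alternatives. These alternatives were another normalization (RLE), DESeq2 1.42.0, no low-count filter, hormone genes left out, no collection covariate, 1 collection method alone, only the compared stages in the fit, batches of 10 or more cells, the Ins1+ Sst+ Ppy+ cell added to the Ins1+ Sst+ cells, other numbers of list genes or no thinning in the share test, mean log2(TPM + 1) over cells with limma, each replicate left out in turn, and a minimum of 2000 genes per cell, which removed 0 cells and so tested nothing. Added after the data were seen were a covariate for the acinar marker level, a covariate for the Xist level, a fit with bias-corrected dispersions, the bulk fit without P15 replicate 2, and the share test without E17.5 batches.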

Results

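The data follow pancreatic β cells, which make insulin, and α cells, which make glucagon, from E17.5 to P60. The 14 bulk libraries of sorted β cells, 2 at each of 7 stages, held 10.3 M to 21.4 M gene reads each. Unselected single β cells numbered 57 at E17.5, 71 at P0, 88 at P3, 65 at P9, 57 at P15, 71 at P18 and 129 at P60, in 3, 3, 5, 3, 3, 3 and 5 batches. Unselected single α cells numbered 65 at E17.5, 46 at P0, 45 at P9, 45 at P15, 44 at P18 and 83 at P60, in 4, 3, 3, 2, 3 and 5 batches. A batch held 5.96 M to 49.1 M reads. The leading axis of a principal component analysis of the bulk libraries held 43.8% of the variance and ran from -100.1 and -79.6 at P0 to 88.4 and 106.7 at P60, while E17.5 (-38.7 and -54.5) lay within the range of P3 (-55.3 and -15.1), which overlapped P9 (-16.9 and 17.1). The second axis held 11.5%. Among the single-cell batches these axes held 20.5% and 9.05%. Per-batch means over cells of log2(TPM + 1), which give each cell the same weight, moved the median of all genes to -0.31 for β cells and -0.44 for α cells between E17.5 and P60, so directions of gene lists that turn on that scale are named beside each list. These means also carry no TMM scaling. A turn may therefore come from the cell weights or from the scaling, which were not told apart.

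The bulk comparison of P60 with E17.5 asked how the β cell transcriptome differs between fetal and adult mice. Ucn3, a peptide of mature β cells, rose from 33.1 ± 1.36 to 565 ± 37.9 CPM (SD, n = 2; log2 change 4.09, adjusted p = 8.1e-07). Ins2, an insulin gene, rose from 44399 ± 2349 to 178402 ± 5396 CPM (log2 change 2.01, adjusted p = 0.000434), and Syt4, a synaptotagmin of secretory granules, rose from 9.20 ± 0.153 to 171 ± 38.8 CPM. Dlk1, a surface protein of immature cells, fell from 1459 ± 278 to 1.40 ± 0.624 CPM (log2 change -10.03, adjusted p = 1.13e-06). Igf2bp3, which binds RNA in fetal tissues, was at least 632-fold lower at P60, with 63.7 ± 7.45 CPM at E17.5 and no read at P60. Gip, an incretin hormone, was at least 377-fold lower, from 38.0 ± 3.59 CPM. Pdyn, the precursor of dynorphin, rose from 0.213 ± 0.0117 to 61.6 ± 10.2 CPM. Ins1 rose from 26188 ± 2040 to 67175 ± 8486 CPM (adjusted p = 0.00369), a call that ended without E17.5 replicate 2 (log2 change 1.28). On GRCm38, Ucn3 (ENSMUSG00000044988) lies on chromosome 13 from 3940688 to 3945349, Dlk1 (ENSMUSG00000040856) on chromosome 12 from 109452823 to 109463336, and Ins2 (ENSMUSG00000000215) on chromosome 7 from 142678656 to 142743381.

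Of 18 genes of β function and maturity, 10 rose, 3 fell and 5 were not called in bulk. Among the risers was Ero1lb, which oxidizes proinsulin in the ER, from 1197 ± 7.47 to 4683 ± 36.1 CPM. Mafa, a transcription factor of mature β cells, stood at 52.3 ± 30.4 and 122 ± 115 CPM and was not called. The list passed camera (adjusted p = 0.00244), with adjusted p = 0.433 with an estimated correlation. Of 15 immature endocrine genes, 13 fell and 0 rose (adjusted p = 2.75e-08, and adjusted p = 0.251 with an estimated correlation). Of 43 proliferation genes, 41 fell and 1 rose (adjusted p = 7.15e-11, and adjusted p = 0.526 with an estimated correlation). Pcna, the clamp of replicating DNA, fell from 76.7 ± 2.23 to 26.3 ± 0.0977 CPM, and Bub1, a mitotic checkpoint kinase, from 19.3 ± 4.97 to 1.33 ± 0.284 CPM. Mki67, a marker of cycling cells, fell from 142 ± 57.9 to 17.4 ± 1.54 CPM (log2 change -3.03), a call that ended without E17.5 replicate 1 (-2.54), P60 replicate 1 (-3.11) or P60 replicate 2 (-2.95). Of 21 genes known as disallowed in β cells, 11 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 7.91e-06, and adjusted p = 0.433 with an estimated correlation). Oat, a mitochondrial aminotransferase of that list, fell from 64.5 ± 0.510 to 4.05 ± 0.420 CPM.

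Of 28 genes of the hormone secretion machinery, 11 rose and 4 fell in bulk (adjusted p = 0.0336, and adjusted p = 0.526 with an estimated correlation). Doc2b, a calcium sensor of exocytosis, fell from 71.4 ± 3.34 to 6.81 ± 1.49 CPM. Among 18 genes of MHC class I and interferon, 8 rose and 1 fell (adjusted p = 0.00652, and adjusted p = 0.314 with an estimated correlation), with B2m, the light chain of MHC class I, at 5.16 ± 0.244 and 32.7 ± 5.31 CPM. Of 49 ribosomal protein genes, 6 fell and 0 rose (adjusted p = 0.00939, and adjusted p = 0.884 with an estimated correlation). The remaining lists did not pass. Of 12 α identity genes, 1 rose and 5 fell (adjusted p = 0.170), and Slc38a5, an amino acid transporter of that list, fell from 381 ± 87.8 to 10.8 ± 2.30 CPM. Of 16 islet transcription factors, 1 rose and 3 fell (adjusted p = 0.195). Of 71 oxidative phosphorylation genes, 2 rose and 5 fell (0.222), and of 14 glycolysis genes, 4 rose and 3 fell (0.922), with Eno2 rising from 8.71 ± 0.726 to 77.5 ± 8.50 CPM. Of 21 genes of ER folding and stress, 2 rose and 5 fell (0.841), of 17 genes of cholesterol synthesis, 4 rose and 1 fell (0.598), and of 13 immediate early and heat shock genes, 0 were called (0.219). In bulk the counts higher and lower when adjusted over the list alone were 12 and 6 for secretion, 9 and 1 for MHC, 0 and 1 for ribosomal, 2 and 6 for α identity, 2 and 0 for oxidative phosphorylation, 4 and 4 for glycolysis and 4 and 6 for ER genes.

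**Figure D1:**
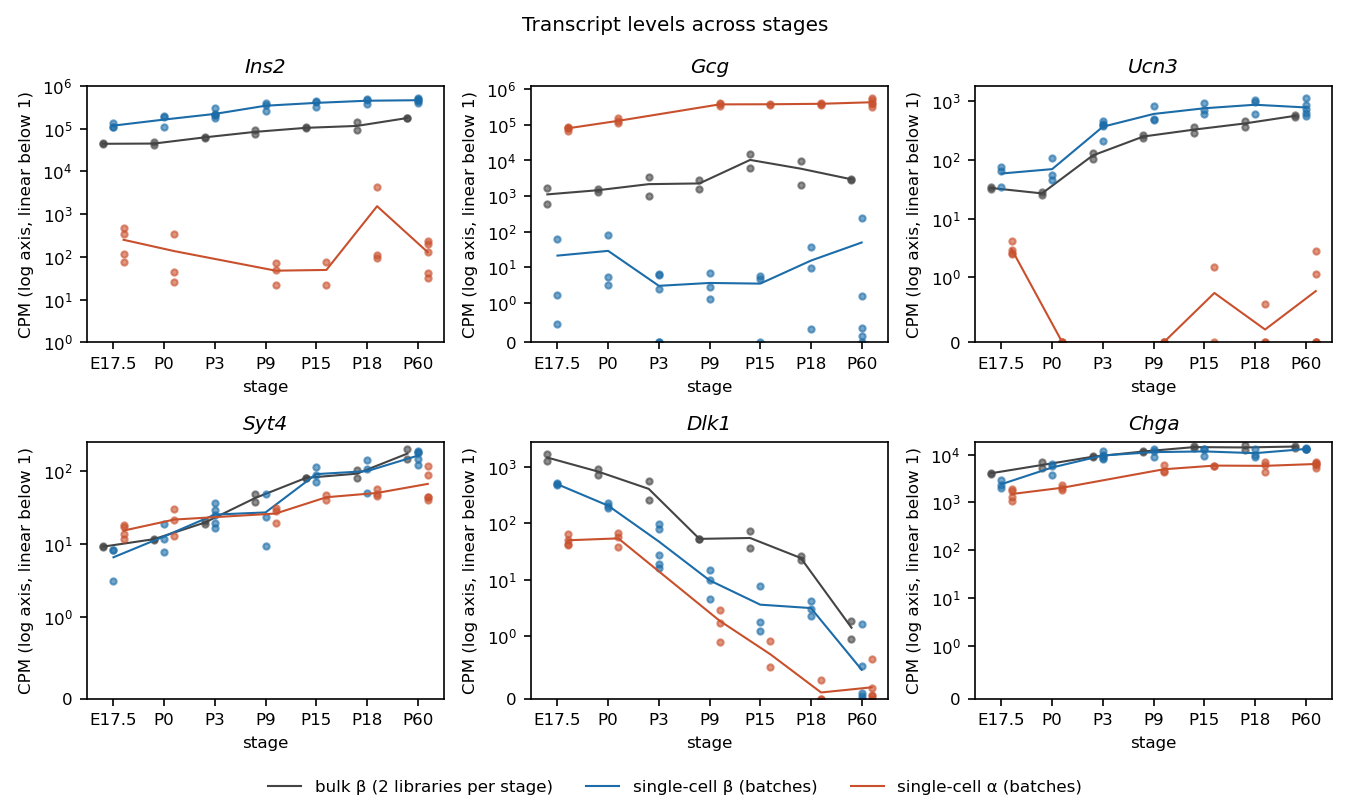
CPM (logarithmic axis, linear below 1) of Ins2, Gcg, Ucn3, Syt4, Dlk1 and Chga by stage in bulk β libraries, single β cell batches and single α cell batches, with points for libraries or batches and lines through the means. Ucn3 reached 565 CPM in bulk and 783 CPM in single β cells at P60, where Dlk1 stood at 1.40 and 0.460 CPM.

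Markers of other cell types also differed in bulk. All 10 acinar genes, which encode digestive enzymes and their partners, were higher at P60. Their summed level was 2811 ± 2144 CPM at E17.5, 476 ± 382 at P0, 22794 ± 4457 at P3, 41573 ± 13427 at P9, 21863 ± 10373 at P15, 19111 ± 5946 at P18 and 34018 ± 23472 at P60. Pnlip, the pancreatic lipase, stood at 0.503 ± 0.228 and 6835 ± 4417 CPM. Of 7 δ cell markers 1 was higher and 3 lower, of 3 PP markers 1 and 1, of 5 ε markers 0 and 3, of 7 duct markers 0 and 4, of 6 endothelial markers 0 and 3, of 6 mesenchymal markers 0 and 4, of 4 erythroid markers 0 and 3, of 4 Schwann markers 1 and 1, and of 6 immune markers 0 and 0. Ghrl, the ε cell hormone ghrelin, stood at 74.2 ± 26.4 and 0.142 ± 0.200 CPM, and Gcg at 1113 ± 741 and 2954 ± 91.9 CPM, which was not called.

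**Figure D2:**
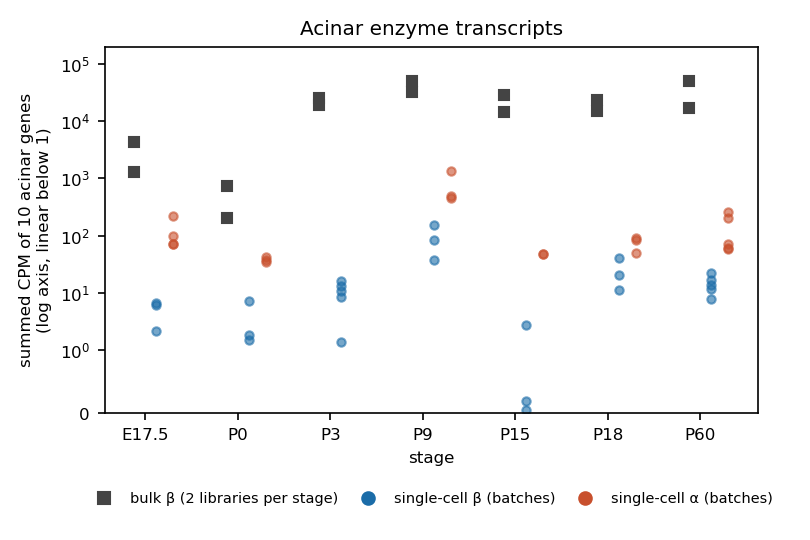
Summed CPM of 10 acinar genes (logarithmic axis) by stage in bulk β libraries and in batches of single β and α cells, each point a library or batch. At P60 the bulk mean was 34018 CPM and the mean over single β cell batches 14.2 CPM.

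In bulk 2224 genes rose and 2452 fell between E17.5 and P60 among 16086 tested (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 1216 and 1758 of these changed more than 2-fold. With 2 libraries per stage the counts rest on single libraries: the rises numbered 1330 without E17.5 replicate 1, 1114 without E17.5 replicate 2 and 1313 without P60 replicate 2, and the falls numbered 1549, 1408, 1454 and 1219 without E17.5 replicates 1 and 2 and P60 replicates 1 and 2. A covariate for the acinar level left 32 rises and 56 falls, and a covariate for the level of Xist, a transcript of female cells that was 563 ± 64.9 CPM at E17.5 and 0.596 ± 0.242 at P60, left 1146 and 1101. The Xist call itself (log2 change -9.85) ended without any 1 of these libraries (-9.73 and -9.96 without E17.5 replicates 1 and 2, -9.49 and -10.35 without P60 replicates 1 and 2).

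Divided at P9, the bulk series held 1316 called genes from E17.5 to P9 (754 higher, 562 lower) and 2610 from P9 to P60 (1093 higher, 1517 lower). Ucn3 stood at 26.8 CPM at P0, 119 at P3, 250 at P9, 328 at P15 and 418 at P18. Between neighbouring stages 479 genes rose and 541 fell from E17.5 to P0, 246 and 148 from P0 to P3, 6 and 6 from P3 to P9, and 131 and 118 from P18 to P60, a sum of 1675 over all steps. From P9 to P15 and from P15 to P18 edgeR called 0 genes with the low-count filter, with 1851 and 912 at an unadjusted p under 0.05. Without that filter edgeR called 771 and 346 in these steps, and DESeq2 called 289 and 11. The early count was 467 and 356 without E17.5 replicates 1 and 2, 530 and 602 without P9 replicates 1 and 2, and 2 with the acinar covariate. The late count was 733 and 1519 without P9 replicates 1 and 2, 1341 and 583 without P60 replicates 1 and 2, and 1565 with the Xist covariate. The sum over steps was 663, 660 and 304 without E17.5 replicate 1, E17.5 replicate 2 and P0 replicate 1, and 142 with the acinar covariate.

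Single β cells addressed the same question in cells taken one by one. Chga, a chromogranin that packs hormone granules, rose from 2394 ± 447 CPM at E17.5 (n = 3 batches) to 13056 ± 376 at P60 (n = 5; log2 change 2.44, adjusted p = 7.51e-11). Ucn3 rose from 58.5 ± 21.8 to 783 ± 226 CPM (log2 change 3.73, adjusted p = 0.000569), and Syt4 from 6.58 ± 2.96 to 160 ± 27.4 CPM (log2 change 4.57, adjusted p = 1.42e-08). Rbp4, a retinol carrier, fell from 945 ± 106 to 9.33 ± 5.66 CPM, and Slc38a5 from 543 ± 248 to 0.952 ± 0.729 CPM. Dlk1 fell from 490 ± 23.6 to 0.460 ± 0.697 CPM (log2 change -10.00, and -11.59 without β P60 batch 3). Slc6a19, an amino acid transporter, had no read at E17.5 and was at least 740-fold higher at P60. Chst8, a sulfotransferase, and Cacna1h, a T-type calcium channel, had no read at P60 and were at least 830-fold and at least 995-fold lower. Ins1 stood at 62925 ± 15627 and 200875 ± 16650 CPM (adjusted p = 0.0642) and Ins2 at 118337 ± 16284 and 464684 ± 47169 CPM (adjusted p = 0.160), neither of which was called. The Ins2 levels of the stages did not overlap (107948 to 137104, then 395860 to 521100 CPM). The fit estimated the spread of a gene over β and α batches together, and α batches held 21.4 to 4400 CPM of Ins2. The missing calls therefore do not show equal insulin levels. Chga (ENSMUSG00000021194) lies on chromosome 12 from 102554969 to 102565028 and Syt4 (ENSMUSG00000024261) on chromosome 18 from 31437808 to 31447406.

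Of 29 genes of the secretion machinery, 13 rose and 0 fell in single β cells (camera adjusted p = 3.12e-06, and adjusted p = 0.00652 with an estimated correlation), while the equal-weight log2(TPM + 1) means turned the list down, with 3 higher and 17 lower. Of 18 genes of β function and maturity, 5 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.00774, and 0.0293 with an estimated correlation), while those means gave 2 higher and 8 lower. Ero1lb rose from 836 ± 125 to 2451 ± 417 CPM, and Mafa stood at 1.42 ± 0.893 and 0.780 ± 0.326 CPM. Of 17 cholesterol synthesis genes, 3 rose and 0 fell (adjusted p = 0.0371, and adjusted p = 0.253 with an estimated correlation), against 1 higher and 6 lower by those means, and Insig1, which restrains that pathway, rose from 25.0 ± 13.4 to 173 ± 12.2 CPM. Of 18 genes of MHC class I and interferon, 5 rose and 0 fell (adjusted p = 3.12e-06, and 0.00135 with an estimated correlation), and B2m rose from 4.82 ± 5.63 to 104 ± 14.3 CPM (log2 change 4.54, and 5.47 without β E17.5 batch 3). Of 16 immature endocrine genes, 1 rose and 10 fell (adjusted p = 3.19e-15, and 4.84e-07 with an estimated correlation). Of 16 islet transcription factors, 0 rose and 6 fell (adjusted p = 1.71e-05, and 0.0293 with an estimated correlation), and of 12 α identity genes, 2 rose and 7 fell (adjusted p = 0.00241, and adjusted p = 0.0636 with an estimated correlation).

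Of 19 disallowed genes tested in single β cells, 0 rose and 2 fell, or 0 and 5 adjusted over the list alone (camera adjusted p = 0.00417, and 0.0269 with an estimated correlation). Oat fell from 90.5 ± 15.6 to 2.44 ± 2.61 CPM (log2 change -5.18, and -5.95 without β P60 batch 3). Of 71 oxidative phosphorylation genes, 2 rose and 12 fell (adjusted p = 1.65e-06), of 21 genes of ER folding and stress, 2 rose and 9 fell (adjusted p = 0.00735), of 49 ribosomal protein genes, 0 rose and 10 fell (adjusted p = 2.14e-08), and of 13 immediate early and heat shock genes, 0 rose and 2 fell (adjusted p = 0.000458). Each of these 4 lists had adjusted p = 0.253 with an estimated correlation. Pdia4, a protein disulfide isomerase, fell from 820 ± 120 to 270 ± 25.2 CPM, and Hsp90b1, an ER chaperone, from 1834 ± 231 to 835 ± 62.8 CPM. Adjusted over the list alone, the counts higher and lower were 2 and 18 for oxidative phosphorylation, 3 and 10 for ER, 0 and 17 for ribosomal, 0 and 8 for immediate early, 3 and 8 for glycolysis, 0 and 7 for transcription factor, 14 and 1 for secretion and 8 and 0 for MHC genes, with the turns under the log2(TPM + 1) means given for each list. Of 14 glycolysis genes, 3 rose and 5 fell (adjusted p = 0.228). Of 43 proliferation genes, 1 rose and 0 fell (adjusted p = 0.466), and Mki67 stood at 2.19 ± 2.85 and 2.33 ± 3.46 CPM. The riser was Spc25, a kinetochore protein, at 34.9 ± 43.0 and 511 ± 129 CPM (log2 change 3.87, and 5.70 without β E17.5 batch 3). Of the markers of other cells, 1 acinar marker was higher, and 1 δ, 1 PP, 2 duct and 1 immune markers were lower, with none called among the ε, endothelial, mesenchymal, erythroid and Schwann markers.

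**Figure D3:**
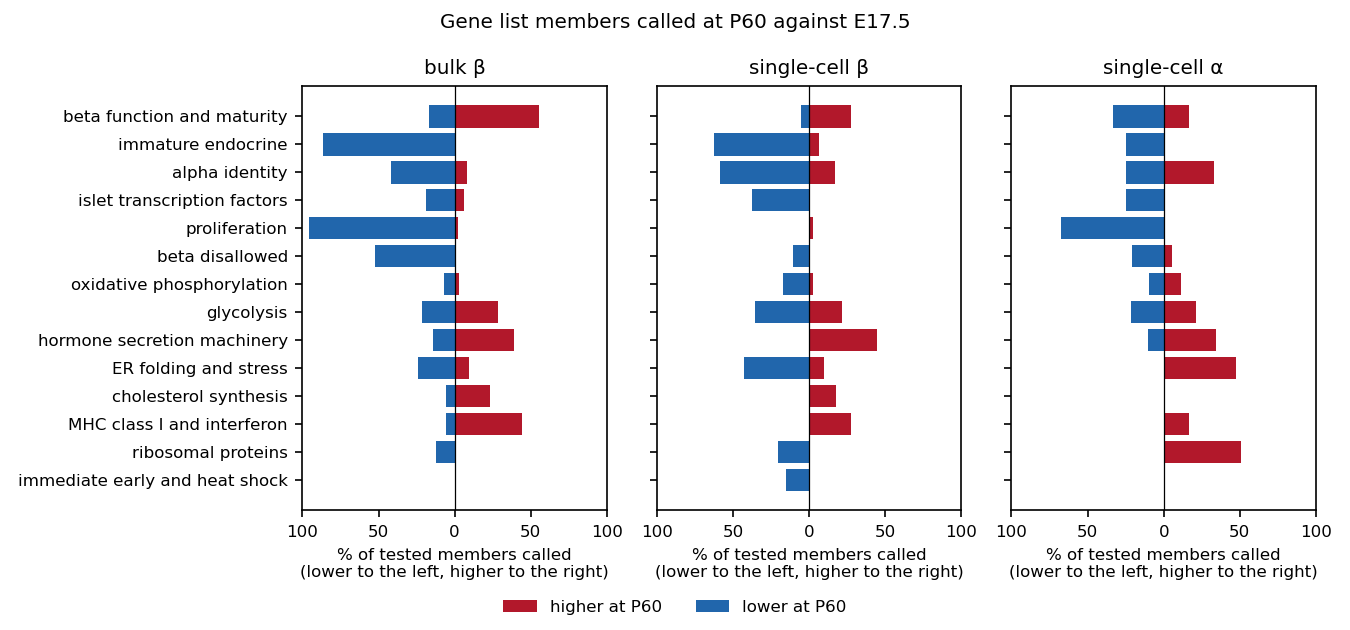
Share of the tested members of each of 14 gene lists that were higher or lower at P60 than at E17.5 (percent) in bulk β libraries, single β cells and single α cells. Of 43 proliferation genes, 41 were lower in bulk, 0 in single β cells and 29 in single α cells.

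In single β cells 571 genes rose and 721 fell from E17.5 to P60 among 18537 tested, 949 of them by more than 2-fold, where the log2(TPM + 1) means gave 375 higher and 6064 lower and DESeq2 981 and 972. Without β E17.5 batch 1 the counts were 302 and 464, and FACS-sorted batches alone gave 60 and 90.

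Single α cells were compared between the same stages. Chga rose from 1486 ± 371 CPM at E17.5 (n = 4 batches) to 6331 ± 755 at P60 (n = 5; log2 change 2.11, adjusted p = 2.84e-10). Pcsk2, the convertase that cuts proglucagon, rose from 2077 ± 473 to 5343 ± 497 CPM (log2 change 1.35, adjusted p = 1.68e-09), and Slc30a8, a zinc transporter of granules, from 314 ± 77.3 to 992 ± 210 CPM (log2 change 1.64, adjusted p = 2.2e-08). Slc38a5 fell from 3775 ± 1407 to 159 ± 75.7 CPM (log2 change -4.55, adjusted p = 1.82e-06). Emid1, an extracellular matrix protein, had no read at P60 and was at least 1349-fold lower, and Gal, the neuropeptide galanin, was at least 1021-fold lower. Dlk1 stood at 49.7 ± 10.8 and 0.180 ± 0.258 CPM and Ghrl at 36.3 ± 41.4 and 0.150 ± 0.217 CPM, both lower at P60, although the sign of Ghrl reversed within hand-picked batches. Gcg, the glucagon gene, stood at 79917 ± 10184 and 432678 ± 96933 CPM (adjusted p = 0.364) and Ppy, the pancreatic polypeptide gene, at 754 ± 260 and 6171 ± 2786 CPM, neither of which was called. The Gcg levels of the stages did not overlap (65578 to 89499, then 311108 to 561652 CPM). The spread was estimated over α and β batches together, and β batches held 0 to 245 CPM of Gcg. The missing call therefore does not show an equal Gcg level. Pcsk2 (ENSMUSG00000027419) lies on chromosome 2 from 143546156 to 143816285 and Slc38a5 (ENSMUSG00000031170) on chromosome X from 8271133 to 8280179.

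Of 43 proliferation genes, 29 fell and 0 rose in single α cells, or 38 and 0 adjusted over the list alone (camera adjusted p = 1.25e-19, and adjusted p = 0.0526 with an estimated correlation). Mki67 stood at 52.6 ± 49.4 and 1.15 ± 2.09 CPM (log2 change -5.97, adjusted p = 0.00442, and -8.14 without α P60 batch 4), and Ccnb2, a mitotic cyclin, at 33.9 ± 36.8 and 0.0123 ± 0.0275 CPM. α E17.5 batch 4 stood apart for Rrm2 of this list (174 CPM against 1.80 to 23.9 in the other E17.5 batches) and for Rpl13 of the ribosomal list (106 against 188 to 198), each in the direction of the change to P60, and the lists were not counted again without it. Of 49 ribosomal protein genes, 25 rose and 0 fell (adjusted p = 3.56e-18, and adjusted p = 0.127 with an estimated correlation), whereas the equal-weight log2(TPM + 1) means gave 0 higher and 28 lower. Rps23 rose from 51.0 ± 14.4 to 125 ± 19.3 CPM. Of 21 genes of ER folding and stress, 10 rose and 0 fell (adjusted p = 4.65e-08, and adjusted p = 0.0526 with an estimated correlation), against 1 higher and 9 lower by those means. Dnajc3, a co-chaperone, rose from 70.4 ± 18.5 to 168 ± 24.0 CPM. Of 29 secretion genes, 10 rose and 3 fell (adjusted p = 3.14e-05, and 0.0446 with an estimated correlation), against 5 and 14 by those means. Among 18 genes of MHC class I and interferon, 3 rose and 0 fell (adjusted p = 0.00892, and adjusted p = 0.0526 with an estimated correlation), against 1 and 4 by those means, and B2m rose from 21.7 ± 8.47 to 106 ± 34.4 CPM.

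Of 16 immature endocrine genes, 4 fell and 0 rose in single α cells (camera adjusted p = 0.00892, and adjusted p = 0.0526 with an estimated correlation), with Mdk, a growth factor, at 28.9 ± 17.1 and 0.299 ± 0.330 CPM. Of 18 genes of β function, 3 rose and 6 fell (adjusted p = 0.0715), of 12 α identity genes, 4 rose and 3 fell (0.428), with 2 and 6 by the log2(TPM + 1) means, and of 16 islet transcription factors, 0 rose and 4 fell (0.186). Of 19 disallowed genes, 1 rose and 4 fell (0.482), of 71 oxidative phosphorylation genes, 8 rose and 7 fell (0.141), with 0 and 64 by those means, and of 14 glycolysis genes, 3 rose and 3 fell (0.501). Of the 17 cholesterol synthesis and 13 immediate early and heat shock genes, 0 were called by edgeR (0.186 and 0.249). Adjusted over the list alone, the counts higher and lower in α cells were 33 and 0 for ribosomal, 12 and 1 for ER, 0 and 5 for immature endocrine, 3 and 9 for β function, 2 and 5 for disallowed, 16 and 8 for oxidative phosphorylation and 3 and 4 for glycolysis genes, with the turns under the log2(TPM + 1) means given for each list. Of the markers of other cells, 1 δ and 1 Schwann marker were higher, and 1 δ, 1 PP, 2 ε, 2 duct and 2 mesenchymal markers were lower. In single α cells 798 genes rose and 1050 fell among 18537 tested, 1361 of them by more than 2-fold, where the log2(TPM + 1) means gave 431 higher and 8823 lower and DESeq2 1171 and 1332. The rises numbered 526 without α E17.5 batch 4, and a covariate for the Xist level left 334 rises and 263 falls. A fit of the α E17.5 and P60 batches alone called 986 genes in all.

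Both cell types were also divided at P9. In β cells edgeR called 131 rises and 101 falls from E17.5 to P9 and 32 and 84 from P9 to P60, and in α cells 404 and 242, then 52 and 105. The log2(TPM + 1) means turned the balance of the early window, with 158 higher and 3842 lower in β and 373 and 6947 in α cells. Fits of the compared groups alone, without the other batches to estimate the spread, called 133 and 103 genes in β cells and 270 and 6 in α cells. Markers of other cells were high in the α P9 batches: summed acinar genes stood at 116 ± 70.8 CPM at E17.5 and 754 ± 496 at P9, and summed erythroid genes at 4.29 ± 4.68 and 523 ± 877 CPM, with 1536 in P9 batch 2 and 14.8 and 18.2 in the others. In β cells the acinar sum stood at 4.94 ± 2.46 CPM at E17.5 and 92.4 ± 59.8 at P9. Ucn3 in single β cells stood at 69.5 CPM at P0, 367 at P3, 606 at P9, 758 at P15 and 871 at P18. In α cells Ghrl stood at 132 CPM at P0, 142 at P9, 25.1 at P15 and 19.7 at P18. The early β count of 232 was 129 without β E17.5 batch 1 and 103 without β P9 batch 2. The late β count of 116 was 74 and 45 without β P9 batches 2 and 3, and 63, 63 and 64 without β P60 batches 2, 4 and 5, and a block for batch number left 70 in β cells and 88 of 157 in α cells.

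The comparison of α with β cells at P60 asked how the 2 cell types differ in the adult. Frzb, a Wnt antagonist, stood at 339 ± 39.3 CPM in β cells (n = 5 batches) with no read in α cells (n = 5), at least 10461-fold lower. Irx2, an Iroquois homeobox factor, stood at 58.0 CPM (30.2 to 78.5 over 5 batches) in α cells with no read in β cells, at least 2168-fold higher. Th, which makes catecholamines, and Mreg, a melanoregulin, were at least 2314-fold and at least 2522-fold lower in α cells. Ttr, the thyroid hormone carrier, stood at 19406 ± 6347 CPM in α and 898 ± 246 CPM in β cells (log2 difference 4.46, adjusted p = 1.37e-13). Ero1lb stood at 125 ± 38.9 and 2451 ± 417 CPM (-4.27, adjusted p = 4.7e-15). Gcg stood at 432678 ± 96933 CPM in α cells and 49.4 ± 109 in β cells (13.55, and 19.91 without β P60 batch 3), and Ins1 at 63.6 ± 56.2 and 200875 ± 16650 CPM. The reporter strain went with the cell type, so strain and cell type cannot be separated. Ttr (ENSMUSG00000061808) lies on chromosome 18 from 20665280 to 20674321 and Frzb (ENSMUSG00000027004) on chromosome 2 from 80411970 to 80447625.

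All 12 α identity genes were higher in α cells at P60 (camera adjusted p = 8.55e-33, and 9.67e-09 with an estimated correlation), and of 18 genes of β function 15 were lower and 0 higher (adjusted p = 1.23e-38, and 5.65e-13 with an estimated correlation). All 49 ribosomal protein genes were higher in α cells (adjusted p = 2.2e-41, and 0.0104 with an estimated correlation), among them Rpl13 at 330 ± 31.6 CPM in α and 119 ± 9.40 in β cells. Of 21 genes of ER folding and stress, 17 were lower in α cells (adjusted p = 1.3e-15, and 0.00208 with an estimated correlation), among them Sdf2l1 at 38.8 ± 11.3 and 199 ± 78.3 CPM. Of 17 cholesterol synthesis genes, 8 were lower (adjusted p = 2.01e-07, and 0.00813 with an estimated correlation), with Sqle, the squalene epoxidase, at 35.1 ± 13.9 and 143 ± 12.5 CPM. Of 29 secretion genes, 2 were higher and 12 lower (adjusted p = 5.49e-05, and 0.00944 with an estimated correlation), against 8 and 4 by the equal-weight log2(TPM + 1) means. Scg2, a secretogranin, stood at 1595 ± 766 CPM in α and 10374 ± 2517 in β cells. Of 16 immature endocrine genes, 5 were higher and 1 lower (adjusted p = 9.63e-05, and 0.00382 with an estimated correlation), and of 19 disallowed genes, 4 were higher and 1 lower (adjusted p = 0.000533, and 0.00484 with an estimated correlation).

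The other lists did not pass between α and β cells at P60. Of 16 islet transcription factors, 5 were higher and 5 lower in α cells (camera adjusted p = 0.792), with 7 and 4 by the log2(TPM + 1) means, and Nkx6-1, a β cell factor, stood at 6.14 ± 3.23 CPM in α and 88.9 ± 15.4 in β cells. Of 71 oxidative phosphorylation genes, 11 were higher and 5 lower (0.0970), of 14 glycolysis genes, 0 and 2 (0.0798), with 2 and 0 by those means, of 43 proliferation genes, 0 and 2 (0.344), with a list median of 0.03 by those means, of 18 MHC genes, 0 and 1 (0.792), with 2 and 0 by those means, and of 13 immediate early genes, 1 and 1 (0.538). Adjusted over the list alone, the counts higher and lower in α cells were 0 and 16 for β function, 0 and 20 for ER, 0 and 9 for cholesterol, 3 and 13 for secretion, 5 and 1 for disallowed, 6 and 7 for transcription factor and 17 and 8 for oxidative phosphorylation genes, with the turns under the log2(TPM + 1) means given for each list. Markers higher in α cells were 2 δ, 2 PP, 2 acinar, 1 duct, 1 mesenchymal and 1 immune markers, and 1 duct marker was lower. At P60 edgeR called 1097 genes higher and 1302 lower in α cells, and at E17.5 602 higher and 938 lower, among 18537 tested. The log2(TPM + 1) means turned this balance, with 2226 higher and 820 lower at P60 and 4240 and 1184 at E17.5, and DESeq2 gave 1524 and 1506, then 1172 and 1138. A fit of the E17.5 batches alone called 974 genes in all.

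A test of the difference itself asked which genes changed from E17.5 to P60 by other amounts in α than in β cells. Oat stood at 29.3 and 107 CPM in α cells at E17.5 and P60 and at 90.5 and 2.44 CPM in β cells (difference of log2 changes 7.03, adjusted p = 1.49e-05, and 7.88 without β P60 batch 3). Iapp, the amylin gene, stood at 2473 and 685 CPM in α cells and at 24141 and 74242 CPM in β cells (-3.41, adjusted p = 0.000345). Hsp90b1 stood at 426 and 638 CPM in α cells and at 1834 and 835 CPM in β cells (1.76, adjusted p = 7.81e-06). Of 49 ribosomal protein genes, 35 had the higher change in α cells and 0 the lower (camera adjusted p = 1.52e-32, and 0.0383 with an estimated correlation). Of 21 genes of ER folding and stress, 10 had the higher change in α cells (adjusted p = 1.11e-11, and 0.00923 with an estimated correlation). Of 16 immature endocrine genes, 4 did (adjusted p = 5.49e-06, and 0.0028 with an estimated correlation), and of 12 α identity genes, 5 did (adjusted p = 0.000361, and 0.0383 with an estimated correlation), against 3 higher and 4 lower by the equal-weight log2(TPM + 1) means. Of 18 genes of β function, 6 had the lower change in α cells (adjusted p = 0.000541, and 0.0076 with an estimated correlation), with a list median of 0.26 by those means.

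Of 43 proliferation genes, 5 had the lower change in α cells and 0 the higher, or 20 and 0 adjusted over the list alone (camera adjusted p = 1.35e-13, and adjusted p = 0.119 with an estimated correlation). Of 71 oxidative phosphorylation genes, 11 had the higher change in α cells (adjusted p = 1.72e-07, and adjusted p = 0.195 with an estimated correlation), with Cox7c at 61.3 and 79.2 CPM in α cells and 81.6 and 44.7 CPM in β cells. Of 16 islet transcription factors, 2 did (adjusted p = 0.0295, and adjusted p = 0.223 with an estimated correlation), and of 17 cholesterol synthesis genes, 4 had the lower change (adjusted p = 0.00305, and adjusted p = 0.151 with an estimated correlation). The disallowed (1 higher, adjusted p = 0.0857), glycolysis (0, adjusted p = 0.784), secretion (1 higher, 2 lower, adjusted p = 0.784), MHC (1 lower, adjusted p = 0.0844) and immediate early lists (0, adjusted p = 0.0650) did not pass, and the secretion list gave 5 higher and 1 lower by the log2(TPM + 1) means. Of the markers, 1 δ and 1 immune marker had the higher change in α cells. In all 680 genes passed, 374 with the higher change in α cells and 306 with the lower, where the log2(TPM + 1) means gave 701 and 1254 and DESeq2 636 and 666. Adjusted over the list alone, the counts with the higher and lower change were 47 and 0 for ribosomal, 12 and 0 for ER, 5 and 1 for immature endocrine, 7 and 1 for α identity, 2 and 9 for β function, 24 and 1 for oxidative phosphorylation, 5 and 0 for transcription factor, 4 and 2 for disallowed, 4 and 4 for secretion and 0 and 3 for MHC genes, with the turns under the log2(TPM + 1) means given for each list.

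β cells enriched for proliferating cells were compared with unselected β cells at P0 and P9, with 1 enriched batch at each stage. Pbk, Foxm1 and Cdk1 had served to choose the enriched cells, so their levels are not evidence here. The other genes of the proliferation list belong to the same process, so a rise of that list follows the selection and is no separate finding. All 40 proliferation genes tested had positive log2 differences, with a list median of 2.76 (camera adjusted p = 2.05e-21, and adjusted p = 0.163 with an estimated correlation), and edgeR called 0 of them over all genes and 2 adjusted over the list alone. Mki67 stood at 309 and 206 CPM in the enriched batches at P0 and P9, and at 86.3 ± 91.9 and 51.5 ± 38.7 CPM in unselected batches (n = 3 each), which was not called. H2afz, a histone variant, stood at 239 and 217 CPM against 91.3 ± 23.1 and 80.5 ± 17.8 CPM (log2 difference 1.45, adjusted p = 0.00172), a call that ended without either enriched batch (1.48 and 1.42). Arl6ip1, an ER-shaping protein, stood at 255 and 534 CPM against 151 ± 44.1 and 102 ± 19.7 CPM (1.61, adjusted p = 0.000856), with 2.43 without the P0 enriched batch and 0.78, no longer called, without the P9 one. Aldoa, a glycolytic aldolase, stood at 119 and 141 CPM against 279 ± 70.4 and 263 ± 36.1 CPM (-1.09, adjusted p = 0.000978), a call that ended without the P0 enriched batch (-0.93).

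Of 14 glycolysis genes, 2 were lower in the enriched cells (camera adjusted p = 0.0149, and adjusted p = 0.212 with an estimated correlation). The ER list (adjusted p = 0.000399, and adjusted p = 0.235 with an estimated correlation), the cholesterol list (adjusted p = 0.00185, and adjusted p = 0.212), the ribosomal list (adjusted p = 0.00463, and adjusted p = 0.806) and the oxidative phosphorylation list (adjusted p = 0.0472, and adjusted p = 0.806) passed downward with 0 members called by edgeR over all genes, at list medians of -0.37, -0.65, -0.24 and -0.15. The lists of β function (0.326), immature endocrine (0.797), α identity (0.126), transcription factors (0.961), disallowed (0.743), secretion (0.688), MHC (0.797) and immediate early genes (0.336) did not pass, and 0 of the markers of other cells was called. The median of all genes was -0.33, below those of the ribosomal and oxidative phosphorylation lists. In all 9 genes were higher and 41 lower among 20445 tested, where 1660 had an unadjusted p under 0.05. The balance turned under the log2(TPM + 1) means, with 440 higher and 56 lower, and under the bias-corrected dispersion, with 128 and 23. Lower when adjusted over the list alone were 4 ER, 2 cholesterol, 2 oxidative phosphorylation and 1 α identity genes. The total of 50 was 5 without the P0 enriched batch, 29 without β P0 batch 2, 82 without β P0 batch 4 and 28 with a block for batch number.

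The share of cells with reads of at least 5 proliferation genes was compared between early and late batches. In β cells it was 91.9 ± 8.30% at E17.5 to P9 (n = 14 batches) and 78.3 ± 16.0% at P15 to P60 (n = 11), a difference of 13.6 points (two-sided permutation test, p = 0.00804). In α cells it was 96.8 ± 4.72% (n = 10) and 83.6 ± 9.53% (n = 10), a difference of 13.1 points (p = 0.00184, permutation). Batches had equal weight, and β P18 batch 3 stood at 40% with 2 of 5 cells. The share did not drop at the boundary used. Over all cells of a stage it was 83.1% at P9 and 86.0% at P15 in β cells, and 91.1% and 97.8% in α cells. Of enriched cells, 9 of 9 at P0 and 11 of 12 at P9 passed this minimum. It does not mark a cell as dividing: 102 of 129 β cells at P60 passed it (79.1%, Clopper-Pearson 95% interval 71.0% to 85.7%). Without thinning the β difference was 2.64 points (p = 0.0320) and the α difference 3.11 (p = 0.0863). Within FACS-sorted batches the β difference was 3.96 points (exact permutation p = 0.439), and within hand-picked ones 21.7 (exact permutation p = 0.00932). The α difference was 14.5 points within FACS-sorted batches (exact permutation p = 0.0216) and 11.7 within hand-picked ones (exact permutation p = 0.111). The thinned reads included hormone reads, whose mean level was higher at P60 than at E17.5, which leaves fewer reads for other genes. Before thinning the median of genes detected was 8582 in β cells at E17.5 and 7624 at P60, and 8610 and 6781 in α cells. Fewer cycling cells and lower detection in late cells cannot be told apart by this share.

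β cells labelled Ins1+ Sst+ were set beside the single-hormone β cells of the same 6 batches. Sst, the somatostatin gene that with Ins1 defined the label, stood at 32139 ± 8729 CPM against 7.21 ± 2.96 CPM. Hhex, a transcription factor of δ cells, stood at 257 ± 194 CPM against 0.190 ± 0.240 (n = 6; log2 difference 10.10, adjusted p = 0.000824), with 10.90 without β P0 batch 1 and 10.78 without β P60 batch 1. Arg1, an arginase, stood at 414 ± 123 against 1.13 ± 0.980 CPM (8.82, adjusted p = 0.000433), and Pyy, the peptide YY gene, at 7161 ± 2962 against 220 ± 185 CPM (5.63, adjusted p = 0.00124). Ins2 stood at 160688 ± 80532 against 326453 ± 167642 CPM (-1.02, adjusted p = 0.0632), Ucn3 at 290 ± 336 against 548 ± 519 CPM and Neurog3, the endocrine progenitor factor, at 26.7 ± 23.2 against 0.480 ± 0.619 CPM, none of them called. Of 6 δ cell markers tested, 4 were higher, Sst included, which the label fixed. Hhex (ENSMUSG00000024986) lies on chromosome 19 from 37434810 to 37440731 and Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484.

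Of 16 genes of β function, 3 were lower in Ins1+ Sst+ cells, or 13 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.584 with an estimated correlation). Of 16 immature endocrine genes, 3 were higher (adjusted p = 0.000159, and adjusted p = 0.133 with an estimated correlation). The ribosomal (adjusted p = 0.000159, and adjusted p = 0.748 with an estimated correlation) and immediate early lists (adjusted p = 0.00583, and adjusted p = 0.337) passed upward relative to the median of all genes, -0.57, with 0 members called by edgeR over all genes. Of 14 disallowed genes, 1 was higher (0.113; list median -0.30, and 1.15 by DESeq2), and of 29 secretion genes, 2 were lower (0.521). The lists of α identity (0.327), transcription factors (0.970), proliferation (0.994), oxidative phosphorylation (0.970), glycolysis (0.970), ER (0.136), cholesterol (0.115) and MHC genes (0.970) did not pass. In all 19 genes were higher and 9 lower among 14590 tested, Sst and Ins1 included, while DESeq2 gave 202 higher and 421 lower, the unpaired fit 22 and 34, and the fit without a low-count filter 22 and 23. Adjusted over the list alone, the counts higher and lower were 4 and 1 for immature endocrine, 0 and 8 for secretion, 0 and 11 for ER, 0 and 3 for α identity, 1 and 3 for transcription factor, 0 and 1 for glycolysis and 1 and 0 for immediate early genes. The total of 28 was 15, 16, 7, 10, 7 and 14 without the pair from E17.5 batch 3, P0 batch 1, P0 batch 2, P9 batch 2, P15 batch 1 and P60 batch 1.

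**Figure D4:**
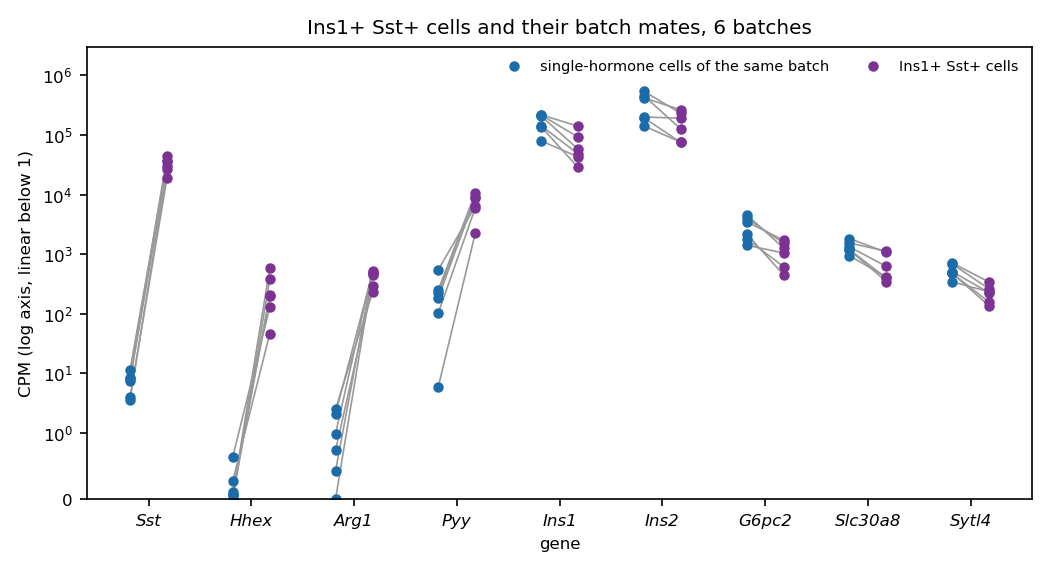
CPM (logarithmic axis) of 9 genes in Ins1+ Sst+ cells and in the single-hormone β cells of the same batch, joined by a line for each of 6 batches. Sst averaged 32139 and 7.21 CPM, and Hhex 257 and 0.190 CPM.

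Bulk and single-cell changes in β cells from E17.5 to P60 were compared across genes, which are not independent replicates. Over 4841 genes called in either, Pearson's r was 0.727 and Spearman's rho 0.806, and 91.6% had the same sign. Of 987 genes called in both, 985 had the same sign: 489 rose in both, where 81.8 would be expected from the margins, and 496 fell in both, where 109 would be. The other 2 were Pla2g1b (6.32 in bulk, -7.55 in single cells) and Tff2 (5.45, -8.25), named after their values were seen. Genes called in 1 data type alone do not enter this count, 3573 in bulk and 281 in single cells. Of 43 proliferation genes, 41 fell in bulk and 0 in single β cells. Ucn3 changed by 4.09 and 3.73, and Syt4 by 4.22 and 4.57.

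**Figure D5:**
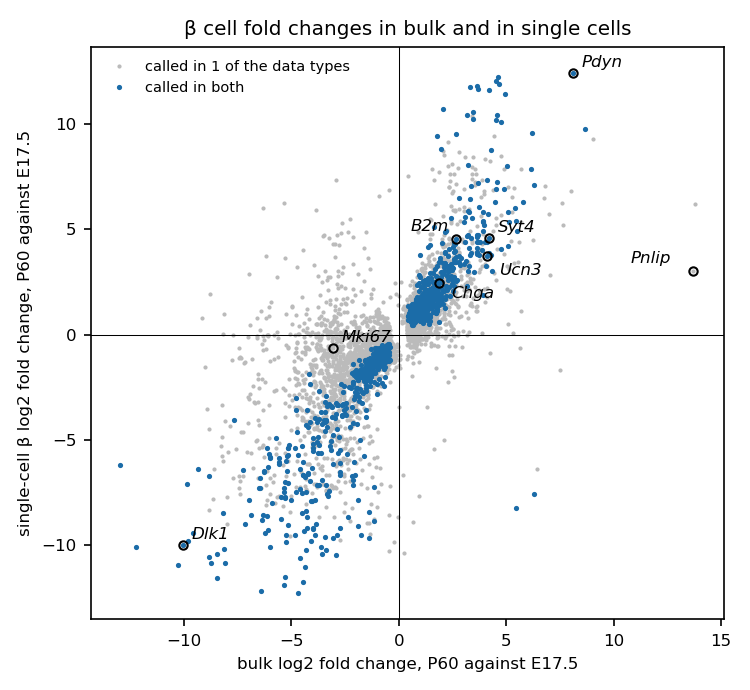
Log2 change from E17.5 to P60 in bulk β libraries (x axis) against single β cells (y axis), each point a gene called in either. Pearson's r was 0.727 over 4841 genes.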

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

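Tests chosen only after the result was seen were the acinar level of single β cells set against bulk, the fold-change ratio with the Xist covariate, the dilution of β cell transcripts in Ins1+ Sst+ cells, and the acinar and Xist covariates.

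Acinar transcripts were high in bulk β libraries from P3 on. The 10 acinar genes moved together between the 2 replicates in 5 of 7 stages: at E17.5 and P0, where their levels were low, and at P9, P18 and P60. At P3 and P15, where levels were high, they did not. RNA of acinar cells in the sorted samples is a candidate source, although the Ins1-RFP sort is meant to remove such cells. Summed mesenchymal genes stood at 728 ± 573 CPM in bulk and 1.48 ± 1.87 in single β cells at P0. At P3 they stood at 658 ± 757 and 1.74 ± 2.86 CPM, while duct genes were alike (456 ± 69.5 and 422 ± 199). The sort need not have kept out all RNA of other cells. In single β cells at P60 the highest batch reached 0.0640% of the bulk P60 level, which argues against transcription of these genes in the β cells themselves. With the acinar level as covariate 4582 of 4676 called genes had the same sign and 88 were called, while standard errors were 2.52 times as wide. The median ratio of fold changes with the covariate to those without was 1.00 (quartiles 0.709 and 1.28). As stage is in that fit, the covariate rests only on acinar differences between replicates of the same stage. The ratio therefore cannot exclude acinar RNA as a source of the fold changes. No other biological explanation was tested for the rise.

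Xist stood at 20 CPM or more in part of the β cells at E17.5, P0 and P3 and of the α cells at E17.5, in 0 of the α cells at P0, in 0 cells at P9, and in 1 of 429 cells from P15 on, while 97.4% of the latter had Y-linked genes at that level. Of 437 cells from E17.5 to P9, 91 reached this minimum for Xist, and 86.8% of these did not reach it for Y-linked genes, so mixed sex in part of the early batches and males later is a candidate explanation. With the Xist level as covariate 2247 bulk genes were called, and sex and stage cannot be told apart for these calls because sex went with stage. The median ratio of fold changes with the covariate to those without was 0.945 (quartiles 0.798 and 1.09), and standard errors were 1.36 times as wide. With stage in the fit, the covariate rests only on Xist differences between replicates of the same stage. The ratio therefore cannot exclude sex composition as a source of the fold changes. Sex as a biological difference stays open.

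Ins1+ Sst+ cells held δ cell transcripts and less Ins1 than their batch mates. They had 1.39 times as many gene reads per spike-in read, higher in 6 of 6 batches (exact p = 0.03125, the smallest these pairs can give), and 1.28 times as many genes detected, also higher in 6 of 6. Of 11 cells, 1 in E17.5 batch 3 went the other way, at 0.434 and 0.872 times its mates. The ratio of reads lay between the values for 1 and 2 cells per well, so 1 and 2 cells cannot be told apart by RNA content. Of the β function genes at 100 CPM or more, 100% were lower (15 of 15, median log2 difference -0.96), as the dilution by a δ cell in the same well may give. Other genes were lower too in the main fit, with a median of -0.57 over all genes and 2 of 71 oxidative phosphorylation genes higher. With RLE the β function list median was -0.76 and 2 of 17 were higher. Cholesterol synthesis then had a median of -0.70 with 0 of 17 higher. Oxidative phosphorylation had -0.12 with 17 of 71 higher, and ribosomal genes 0.17 with 42 of 49 higher. How far the share lower is particular to β function genes therefore depends on the scaling. A single cell with both hormones stays open.

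Other splits of the same batches were counted for 10 single-cell comparisons, in fits of the compared groups alone, and not for bulk or enriched cells, with fewer than 3 samples in a group. Of 126 possible splits for α P60 against E17.5, 126 for α against β at P60 and 8820 for the difference between α and β changes, 100 each were drawn, the real one included. Among the splits counted, only the real one had as many genes called in each of the 10, and chance can be excluded for β P60 against E17.5 (1676 genes, highest other 2), α P60 against E17.5 (986, highest other 4), β P60 against P9 (103, highest other 1), α P9 against E17.5 (270, highest other 1), α P60 against P9 (6, highest other 1), and α against β at E17.5 (974, highest other 0) and at P60 (2308, highest other 29). For Ins1+ Sst+ cells (28, highest other 10) Sst and Ins1 set the label and are among the genes counted. Genes that go with Sst follow the same choice of cells. The splits therefore cannot exclude chance for that count. For the difference between α and β changes (644, highest other 399) the splits exchanged α and β labels within a stage. The highest came from a split that exchanged all α and β batches at P60 and 1 of each at E17.5. Such splits carry the difference between the cell types into the spread or into the tested difference, so they cannot exclude chance for this count. For β P9 against E17.5 (133, highest other 0) the 10 splits are too few for a share under 0.05. The counts of these fits differ from those of the fit over all groups, as 6 against 157 for α P60 against P9 and 270 against 646 for α P9 against E17.5, and the splits speak only to the former.

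In 33 of 255 groups of values 1 batch lay far from the others by Dixon's test of the gap to the nearest value. Chance gives about 1 in 20 only for independent, normally distributed values. A group with reads in 1 batch alone is always flagged, as for Higd1a, Edn3 and Adamts18 in β cells at P60, and genes of the same batch are not independent. The 33 groups can therefore not be set against that rate. Among β cells at P60, batch 3 was highest for Mki67 (8.37 CPM), Edn3 (0.0412), Gcg (245), Rrm2 (25.8), Ppy (22.1), Ccnb2 (2.47) and Slc14a2 (28.3) and lowest for Rpl13 (102). There batch 1 was highest for Higd1a (0.0591) and Zfp36 (71.4), batch 4 for Adamts18 (0.0397), and batch 2 was lowest for Ins1 (171212). Among α cells at E17.5, batch 4 was highest for Ache (0.923), Ncaph (111) and Rrm2 (174) and lowest for Atp5e (77.3) and Rpl13 (106), batch 1 was highest for Slc24a2 (1.18), and batch 2 for Slc6a19 (1.16) and Tmem255a (0.835). Among α cells at P60, batch 3 was highest for Dlk1 (0.630) and Ghrl (0.525) and lowest for Atp5e (163) and Ppy (1301), batch 4 was highest for Rrm2 (0.0592) and Mki67 (4.86) and lowest for Atf4 (98.9), batch 2 was highest for Ccnb2 (0.0616) and Zfp36l1 (0.185), batch 1 for Cat (0.544) and batch 5 for Mdk (0.871). Among Ins1+ Sst+ cells, Cbln4 (207) was highest in P15 batch 1 and Neurog3 (70.2) in P0 batch 2.

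The change from E17.5 to P60 differed between α and β cells for 680 genes by the test of the difference. The fitted differences of log2 changes were 12.78 for Adamts18, 12.02 for Higd1a, 10.80 for Lrtm2, 9.50 for Fev, 9.47 for Dnah11, -17.31 for Slc6a19, -17.12 for Tmem255a, -13.84 for Ccnb2, -13.25 for Slc14a2, -13.02 for Emid1, -11.09 for Rrm2 and -5.57 for Ucn3, which hold groups near 0 reads and are no bounds. They were 7.03 for Oat, 4.48 for Slc38a5, 1.76 for Hsp90b1, 1.53 for Pdia3, 1.38 for Rpl13, 1.33 for Cox7c, 1.18 for Atp5j2 and 1.02 for Rpl15. They were -5.72 for Sytl4, -3.51 for Spc25, -3.41 for Iapp, -3.06 for Ins1, -2.84 for Msmo1, -2.36 for Syt4, -2.24 for Insig1 and -1.17 for Tapbp. The sign for Sytl4 reversed by the log2(TPM + 1) means and in hand-picked batches. Leaving out 1 batch ended the call of Slc6a19 (-11.66 without α E17.5 batch 2), Tmem255a (-17.17, -17.04 and -17.10 without β E17.5 batches 1, 2 and 3, -11.93 without α E17.5 batch 2), Ccnb2 (-9.96 without β P60 batch 3), Msmo1 (-2.80 and -2.67 without β E17.5 batches 1 and 2, -2.52 and -2.68 without α E17.5 batches 3 and 4) and Tapbp (-1.18 and -1.09 without β E17.5 batches 1 and 2, -1.10, -1.13 and -1.15 without β P60 batches 2, 3 and 4, -1.16 and -0.95 without α E17.5 batches 1 and 4, -1.02, -1.04 and -1.12 without α P60 batches 2, 3 and 4). It moved Adamts18 (11.69 without β E17.5 batch 3, 14.24 without α E17.5 batch 2, 14.20 without β P60 batch 4), Higd1a (11.36 without β E17.5 batch 3, 14.08 without β P60 batch 1), Lrtm2 (9.95 without β E17.5 batch 1, 10.14 without α P60 batch 1), Fev (10.46 without β P60 batch 3), Dnah11 (8.33 without β E17.5 batch 2), Ccnb2 (-15.23 and -13.13 without β E17.5 batches 1 and 2, -12.13 without α E17.5 batch 2, -15.20 without α P60 batch 2), Ucn3 (-6.97 without α P60 batch 5), Spc25 (-5.36 without β E17.5 batch 3, -2.76 without α E17.5 batch 4), Rrm2 (-10.50 and -13.36 without β E17.5 batches 1 and 3, -9.97 without α E17.5 batch 4, -12.49 without α P60 batch 4), Oat (7.88 without β P60 batch 3) and Sytl4 (-4.54 without α E17.5 batch 1).

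Signals also appeared in data outside the comparisons. Bulk libraries held 7 spike-in reads in E17.5 replicate 2, 8 in P15 replicate 2 and 7 in P18 replicate 2. The 4 Ngn3-GFP cells at P0 are labelled as without hormone and differed widely, with Ins1 from 49.0 to 8447 CPM and Ins2 from 168 to 36166, where α batches at P0 held 25.2 to 341 CPM of Ins2 and α P18 batch 2 held 4399.8. Pooled they held 51.1 CPM of Neurog3, 2174 of Ins1, 12624 of Ins2, 5469 of Pyy and 10710.1 of Chga.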

How the results depend on the processing

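Tests chosen only after the result was seen were the acinar and Xist covariates, the bias-corrected dispersion, the bulk fit without P15 replicate 2 and the share without E17.5 batches. Of 3839 alternative values of 196 named and called genes, 3465 kept direction and side of the threshold, 369 kept direction only and 5 reversed. Another size factor (RLE), hormone genes left out and no collection covariate moved no total of called genes by more than 1.5 times, although RLE gave 12 higher and 26 lower in enriched cells and 24 and 3 in Ins1+ Sst+ cells, and no collection covariate 21 rises in β P60 against P9. With 2 bulk libraries per stage and 2 to 5 batches per group, depth and number limit calls of genes with few reads. The cause was not tested for the changes below, except that fewer samples enter the FACS, hand-picked, large-batch and leave-one-out refits.

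With the acinar covariate bulk P60 against E17.5 gave 32 higher and 56 lower, P9 against E17.5 gave 2 and the steps 142. With the Xist covariate bulk gave 1146 and 1101, P60 against P9 1565, α cells 334 and 263, and α P9 against E17.5 265. Without a low-count filter bulk P9 against E17.5 gave 2131, the steps 7144, enriched cells 33 and Ins1+ Sst+ cells 45. By DESeq2 the steps gave 4452, β rises 981, β P9 against E17.5 672, β P60 against P9 414, α 1383 and 726 for these windows, the interaction 1302, enriched cells 413 and Ins1+ Sst+ cells 623. By equal-weight log2(TPM + 1) means, which carry no TMM scaling, β gave 375 higher and 6064 lower, α 431 and 8823, the β windows 4000 (158 higher, 3842 lower) and 185, the α windows 7320 (373 higher, 6947 lower) and 392, α against β at E17.5 5424, the interaction 1955 and enriched cells 496. FACS-sorted batches gave β 60 and 90, α 272 and 299, β windows 20 and 1, α windows 287 and 54, α against β 526 at E17.5 and 892 at P60, and the interaction 64. Hand-picked batches gave β 314 and 270, α 464 and 279, β windows 93 and 24, α windows 255 and 51, α against β 802 and 1256, and the interaction 367. Batches of at least 10 cells gave α 339 and 521, β P9 against E17.5 149, α 198, α against β at E17.5 723, the interaction 275 and enriched cells 5. The bias-corrected dispersion gave β 1043 and 1114, α rises 1297, β windows 630 and 278, α windows 1088 and 324, α against β at E17.5 2744 and enriched cells 151. A block for batch number gave β P60 against P9 70, α 88 and enriched cells 28. Ins1+ Sst+ cells unpaired gave 56. Of the list tests 52 passed with the preset correlation and 20 with the estimated one.

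With 1 library or batch left out the counts ranged as follows: bulk higher 1114 to 2238 and lower 1219 to 2475, P9 against E17.5 356 to 1360, P60 against P9 583 to 2864, steps 304 to 1866, β higher 302 to 526 and lower 464 to 607, α higher 526 to 788 and lower 755 to 939, β windows 103 to 177 and 45 to 101, α windows 431 to 566 and 113 to 180, α against β 1040 to 1396 at E17.5 and 2016 to 2194 at P60, interaction 454 to 685, enriched cells 5 to 82 and Ins1+ Sst+ cells 7 to 16.

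The early minus late share of cells with proliferation genes was 0.971 points in β (p = 0.351) and 0.625 in α cells (p = 1) with a minimum of 3 genes, 3.96 in FACS-sorted β (p = 0.439), 3.11 in α without thinning (p = 0.0863) and 11.7 in hand-picked α batches (p = 0.111). In β cells it was 2.64 without thinning (p = 0.0320) and 21.7 in hand-picked batches (p = 0.00932), and in FACS-sorted α batches 14.5 (p = 0.0216). It passed with a minimum of 10 genes (19.4 and 44.3 points) and without E17.5 batches (12.1 and 11.0). Pearson's r between bulk and cells was 0.897 over genes called in both and 0.592 over all genes.

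Signs of log2 values reversed as follows. Bulk Mafa was -0.33 without P60 replicate 1 (1.99 without E17.5 replicate 2), -0.64 with the acinar and -0.25 with the Xist covariate. In single β cells Mafa was 0.84 in FACS-sorted batches, Tapbp was -0.12 by the log2(TPM + 1) means, and Mki67 was 0.032 without the collection covariate, 0.020 with a block, 2.16 in hand-picked batches, 0.089 with the Xist covariate and 2.05 without β E17.5 batch 3 (-1.71 without β P60 batch 3). In α cells the log2(TPM + 1) means gave Ppy -1.03, and hand-picked batches Ghrl 1.46. By those means Aldoa in α against β at P60 was 0.055, and in the interaction Sytl4 was 2.12, with 3.70 in hand-picked batches.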

Other observations

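Cells labelled with more than 1 hormone, other than Ins1+ Sst+ cells, numbered 1 to 3 per label and stage and were not tested. In α cells labelled Gcg+ Ghrl+, Ghrl ranged from 4450.3 to 14992 CPM over 2 cells at E17.5 and from 3732 to 7716.5 CPM over 3 cells at P0, and Gcg from 27095 to 207518 CPM and from 175329 to 235722 CPM. In α cells labelled Gcg+ Ins1+ at P0, Ins1 ranged from 9754 to 100490 CPM over 2 cells, Gcg from 130112 to 171992 CPM and Ucn3 from 31.8 to 37.2 CPM. A Gcg+ Ppy+ Sst+ cell at P18 held 305647 CPM of Gcg, 27863 of Sst and 9063 of Ppy. A β cell labelled Gcg+ Ins1+ at P60 held 179511 CPM of Gcg and 68297 of Ins1.

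Gene reads per spike-in read of single cells averaged 30.0 ± 4.24 in β cells at E17.5 (n = 3 batches) and 53.7 ± 7.97 at P60 (n = 5), and 23.6 ± 6.06 (n = 4) and 33.3 ± 17.3 (n = 5) in α cells. This ratio follows RNA content only if each cell got the same amount of spike-in, which was not checked. Batch ranges at the 2 stages were apart in β cells (25.1 to 32.7, then 43.1 to 59.6) and overlapped in α cells (19.9 to 32.6, then 12.8 to 58.9). β P3 batches alone ranged from 37.9 to 76.1. Mki67 in bulk β libraries stood at 142 CPM at E17.5 and 17.4 at P60, while in single β cells it stood at 2.19 CPM at E17.5, 86.3 at P0 and 2.33 at P60. Xist stood at 20 CPM or more in 42.1% of β cells at E17.5, 38.0% at P0, 19.3% at P3, 0 of 65 at P9 and 1 of 129 at P60, and in 35.4% of α cells at E17.5 and 0 of 46 at P0.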
